A study of Mus musculus with 72 samples.

How the data were processed

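The labels give TRIzol extraction of total RNA and TruSeq RNA libraries, 72 in all, from 6 tissues of EGFR DEL19 transgenic mice. Lung tumour, lung, liver, kidney, spleen and thymus were each measured in 12 libraries, 4 for each of 3 injected circuits. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. Only DESeq2 is named in the processing notes, without a version or a role. Per the labels and the deposited values, each tissue has a table of signal values that the authors made by dividing gene counts by size factors, with each tissue scaled on its own. The values are fractional, and between 50.1% and 72.2% of the low values of a library were whole multiples of its recurring step, so read counts could not be recovered from them. The step was the most frequent value under 5 in a library, low values were those of up to 20 steps, and a whole multiple was one within 0.1 of a step. Of 36047 mouse gene identifiers, 35968 carried the version of GENCODE M21 and 79 did not. The tumour table also holds a human EGFR transcript, ENST00000275493.7, which the tables of the other tissues lack.

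Because the values are already normalized, they were analysed with limma 3.58.1 in R 4.3.3 (limma-trend) on log2(value + 1), in place of the count model that had been planned for read counts. Genes with a value of at least 10 in at least 4 of the 12 libraries of a tissue were tested. All 12 libraries of a tissue entered a fit with 1 mean per circuit and no covariate, from which 3 comparisons were drawn. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. Fold changes are on the log2 scale with the standard error of the fit. Human EGFR and mouse Egfr were also compared by two-sided exact permutation of the 8 libraries, adjusted over 21 tests, on log2(value + 1) and on values rescaled to a common column total (CPM).

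Before the data were examined, 43 gene lists, the rule for naming genes and the main settings were fixed. A named gene passed the test, had a mean of at least 1 CPM, separated all 4 libraries of a group from all 4 of the other, and had a symbol other than a predicted or clone name. The 10 highest and 10 lowest such genes were taken in tumour, 5 each way in lung and 4 each way in the other organs. Up to 4 further members that passed were added from each list, or up to 2 of the most abundant members of a list with no member that passed. The text names the genes that the rule gave each way and part of those from the lists, except some that are not reported here. Genes outside the rule are marked as chosen after their values were seen. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists and 3 comparisons of a tissue, and again with a correlation estimated from the data. Fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes, was run as an alternative.

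The 4 control libraries of a tissue served both comparisons with the control. The correlation of their fold changes was therefore set beside 100 simulations of unchanged groups against the same controls, and beside a version in which each comparison used a different 2 of the controls. On simulated changes in 200 genes of each tissue, limma called between 41% and 72% of the changes of 1 log2 unit in the 5 organs and 14% in tumour, and between 72% and 95% of the changes of 2 log2 units, with 4 to 9 false calls a tissue. The simulated noise was independent between genes and had the same spread in all groups. It leaves out libraries that stand apart across many genes, so these shares need not hold where such libraries occur.

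Alternatives planned beforehand were a pseudocount of 0.1, no filter on low values, a fit of only the 8 libraries compared, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were scaling by the column total, scaling by the total without mitochondrial genes, the mitochondrial share, Ddx3y or Dbp as a covariate, and fits of kidney and thymus without CMV-GE11-siRE replicate 4. The tumour and lung tables were normalized separately, so the planned comparison of tumour with lung and the planned differences of effect between them were not made. Nothing in the labels says that the libraries of a group come from separate animals, so the p-values measure the spread between these samples.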

Results

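The data were gene-level RNA sequencing values of lung tumours and 5 organs of mice whose lungs express a human EGFR with the DEL19 mutation, which makes this growth factor receptor active without its ligand. The mice had received by injection 1 of 3 DNA circuits driven by the CMV promoter, which make the body's own cells produce small RNAs. CMV-scrR carries a scrambled RNA and served as the control, CMV-siRE carries an siRNA against EGFR, and CMV-GE11-siRE carries the same siRNA with GE11, a peptide that binds EGFR. Each circuit had 4 libraries in each tissue, 72 in all. The approximate depth, taken as the column total over the recurring smallest value, was 12.2 M to 20.9 M with a median of 19.2 M. With M as the prefix mega throughout, normalized column totals were 16.9 M to 21.38 M in the 5 organs and 5.87 M to 43.81 M in the tumours. Between 15523 and 21522 genes had a value above 0 in a library. Since the values are normalized estimates, no counting interval was attached to them, and the spread between libraries is the measure of precision.

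The series asks whether the circuits lower EGFR in the tumour, and human EGFR is the transcript closest to that question. The labels give 25 days of doxycycline. Neither the induction of the transcript nor the share of cells that carry it was measured, so its level alone does not settle the question. Human EGFR (ENST00000275493.7) had a normalized value of 2999.7 ± 850.0 (SD, n = 4) in tumours given CMV-scrR, 845.9 ± 366 with CMV-siRE and 85.7 ± 38.4 with CMV-GE11-siRE. With CMV-GE11-siRE it fell by 5.19 ± 0.38 (log2, SE) against CMV-scrR (limma adjusted p = 2.19e-05). Against CMV-siRE it fell by 3.31 ± 0.38 (adjusted p = 0.00635). The difference between CMV-siRE and CMV-scrR was -1.88 ± 0.38 and did not pass (adjusted p = 0.055). All 4 libraries of the lower group lay below all 4 of the other in each comparison. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 allows, or 0.12 after adjustment over 21 tests. As CPM, values rescaled to a common column total, the means were 98.1 ± 9.44, 44.7 ± 28.7 and 12.5 ± 6.37 (SD, n = 4). The differences in log2(CPM + 1) were -3.0, -1.63 and -1.37 in the order of those comparisons, with exact permutation p = 0.0286, 0.0571 and 0.0286 (0.12, 0.2 and 0.12 after adjustment). Without CMV-scrR replicate 4, CMV-siRE replicate 2 or CMV-siRE replicate 3 the difference of CMV-siRE from CMV-scrR passed, at -1.84, -1.62 and -1.84, as it did with Ddx3y as a covariate, at -1.85. In a fit of only the 8 libraries the fall against CMV-siRE, at -3.31, did not pass. With the mitochondrial share as a covariate neither fall with CMV-GE11-siRE passed, at -5.25 ± 0.95 and -3.36 ± 0.81 (adjusted p = 0.99 and 1). Reads of human EGFR and mouse Egfr can be shared where the sequences are alike, so the split between both is uncertain.

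**Figure D1:**
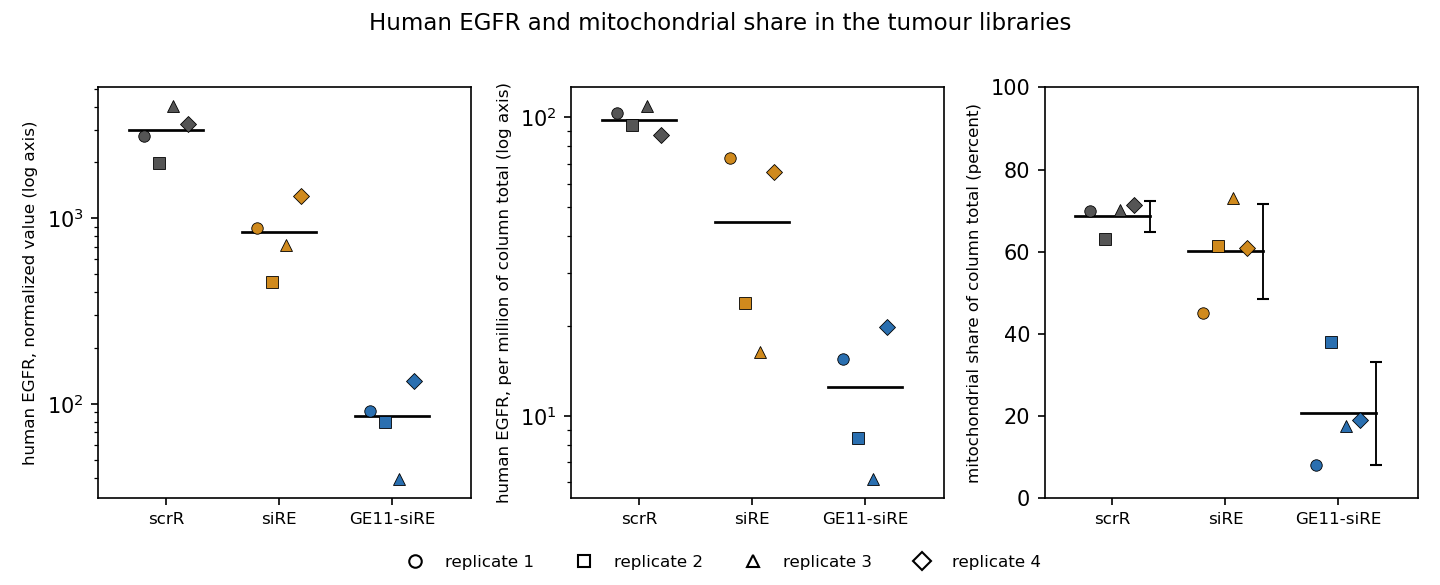
Human EGFR in each tumour library as a normalized value and as CPM (log axes), and the mitochondrial share of the column total in percent; horizontal lines are means of 4 libraries, error bars on the right panel are SD, and symbols give the replicate number. The normalized means were 2999.7, 845.9 and 85.7, and the mitochondrial share averaged 68.6%, 60.1% and 20.6% in the same order of circuits.

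Mouse Egfr (ENSMUSG00000020122.16), the protein-coding gene of the same receptor on the + strand of chromosome 11 at 16752203 to 16918158 in GRCm38, was measured in all 6 tissues. In liver it had 5026.4 ± 549 (SD, n = 4) with CMV-scrR, 4601 ± 264 with CMV-siRE and 3876.7 ± 159 with CMV-GE11-siRE. It fell by 0.37 ± 0.08 (log2, SE) with CMV-GE11-siRE against CMV-scrR (limma adjusted p = 0.028, exact permutation p = 0.0286, or 0.12 after adjustment). That call was lost when CMV-scrR replicate 2, 3 or 4 or CMV-GE11-siRE replicate 1, 2 or 3 was left out, at -0.35, -0.38, -0.31, -0.36, -0.36 and -0.36, and in a fit of only the 8 libraries (-0.37) or with the mitochondrial share as a covariate (-0.38). The liver differences of CMV-siRE from CMV-scrR and of CMV-GE11-siRE from CMV-siRE, -0.12 and -0.25, did not pass. Elsewhere Egfr did not pass in any comparison with the values as given. Its differences of CMV-siRE, then CMV-GE11-siRE, from CMV-scrR were -0.36 and -0.17 in lung, -0.04 and -0.09 in kidney, -0.38 and -0.01 in spleen, 0.12 and -0.09 in thymus, and -0.11 and 0.45 in tumour. Between CMV-GE11-siRE and CMV-siRE they were 0.19 in lung, -0.06 in kidney, 0.37 in spleen, -0.21 in thymus and 0.56 in tumour. The tumour values depended on the scaling. In log2(CPM + 1) Egfr in tumours given CMV-GE11-siRE differed from CMV-scrR by 1.78, with all 4 libraries above all 4 others (exact permutation p = 0.0286, or 0.12 after adjustment). Scaled by the column total it passed in limma against CMV-scrR (2.49) and against CMV-siRE (2.08), and with the mitochondrial share as a covariate the 2 differences were -1.73 and -1.24. The difference of CMV-siRE from CMV-scrR was 0.41 by column total and 0.09 without mitochondrial genes.

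Tumours given CMV-siRE differed from those given CMV-scrR in 36 genes, of which 31 rose and 5 fell (n = 4 libraries a group). The genes that rose most were Lrrc7, a scaffold protein of synapses, by 5.42 ± 0.7 (log2, SE; adjusted p = 0.0111), Pagr1a by 4.07 ± 0.65 and Npff, a neuropeptide precursor, by 3.11 ± 0.42. Ipo13, which carries proteins into the nucleus, rose by 2.55 ± 0.29 (adjusted p = 0.00687), and Nxf1, which exports mRNA from it, by 2.47 ± 0.38. Usp13, Plcd3, Slc4a8, Pomt2 and Adck5 rose by 2.24 to 2.45. Fam198b fell by 1.89 ± 0.3, and the 4 others that fell, chosen after their values were seen, included the Notch target Hey1 (-1.51 ± 0.29) and Smad7 (-1.45 ± 0.2), an inhibitor of TGF-beta signalling.

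No list had a member that passed in this comparison, and 7 lists were called by the preset test. The alveolar type 2 list, markers of the surfactant-making cells of the lung, had a median of 1.28 over 16 members, 12 of them higher when adjusted over the list alone. Its most abundant members in these tumours, Sftpc and Sftpa1, differed by 1.62 ± 0.65 and 0.96 ± 0.42. The EGFR family list had a median of 1.26 with 4 of 9 higher adjusted over the list alone, and the MAPK and EGFR feedback list 0.5 with 5 of 17. The medians were below 0 for club cells (-1.55), ciliated cells (-1.21), macrophages (-0.72) and endothelium (-0.7, 2 of 13 lower adjusted over the list alone). All 7 medians had the same sign under the other scalings. This follows from their size, since each scaling moves all genes up by a nearly constant amount, and it tests no list. With an estimated correlation none of these calls held (adjusted p = 0.979 for each). Scaled by the column total, the median of all genes moved by 0.48 and the count became 11, all higher. Scaled by the total without mitochondrial genes it moved by 0.18 and the count became 14, all higher. Leaving out 1 library gave 13 genes without CMV-scrR replicate 2, 14 without CMV-scrR replicate 3, 285 without CMV-scrR replicate 4, 10 without CMV-siRE replicate 1, 614 without CMV-siRE replicate 2, 798 without CMV-siRE replicate 3 and 1 without CMV-siRE replicate 4. The count was 0 in a fit of only the 8 libraries, 16 with no filter on low values, 7 with the mitochondrial share as a covariate and 1100 with Ddx3y as a covariate.

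With CMV-GE11-siRE against CMV-scrR, 5890 of 14044 genes changed in the tumours, 3107 rising and 2783 falling (n = 4 a group). The mitochondrial share moved with the circuit: it was 68.6% ± 3.77 of the column total with CMV-scrR, 60.1% ± 11.6 with CMV-siRE and 20.6% ± 12.5 with CMV-GE11-siRE (SD, n = 4). Scaling by the column total moved the median of all genes in the comparison of CMV-GE11-siRE with CMV-scrR from 0.05 to 2.11 and the counts to 11377 higher and 58 lower. Scaling without mitochondrial genes moved it to 0.8 and the counts to 6065 and 610. Each scaling moves all genes up by a nearly constant amount, so which calls stay follows from the size of a change and tests no single gene. Of 2783 genes called lower 57 stayed lower under both, of which 13 are mitochondrially encoded, 24 are predicted genes with Gm names and 1 is human EGFR. With the mitochondrial share as a covariate 0 genes passed in limma, and human EGFR was at -5.25 ± 0.95. The genes and lists below are given for the values as deposited.

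Alveolar type 2 genes rose in this tumour comparison: of 16 members 14 rose and 1 fell, with a median of 2.25, and the same number of each passed adjusted over the list alone. Abca3, which loads surfactant lipid into lamellar bodies, rose by 2.95 ± 0.43 (log2, SE; adjusted p = 0.00058), the phosphate transporter Slc34a2 by 2.77 ± 0.43, the surfactant phospholipid enzyme Lpcat1 by 2.74 ± 0.38 and Lamp3 by 2.0 ± 0.32. Of 9 members of the EGFR family list 7 rose and none fell, with a median of 2.15, among them the partner receptors Erbb2 by 2.87 ± 0.46 and Erbb3 by 2.56 ± 0.43. Of 17 MAPK and EGFR feedback members 7 rose, 2 fell and 8 did not pass; the ETS factor Etv4 rose by 2.93 ± 0.59, Phlda1 by 1.98 ± 0.35 and the signalling inhibitor Spry1 by 1.32 ± 0.27. The list calls for alveolar type 2 and EGFR family genes were lost with an estimated correlation (adjusted p = 0.979 for each).

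Among the tumour genes that rose most were Aldh3b3, an aldehyde dehydrogenase, by 6.28 ± 1.26, the P-type ATPase Atp13a4 by 5.77 ± 0.97 and the sialyltransferase St6galnac2 by 5.25 ± 0.72, with Col26a1, Mesp1, Ighg2b, Cdh24, Lrrc7 and Rgs11 between 4.61 and 5.27. Srebf1, which drives fatty acid synthesis genes, rose by 3.45 ± 0.44, the angiogenic factor Vegfa by 3.32 ± 0.57 and the glucose transporter Slc2a1 by 1.98 ± 0.49. The clock genes Per2 and Per3 rose by 2.54 ± 0.3 and 2.42 ± 0.29, and of 15 clock members 6 rose, 2 fell and 7 did not pass. In the cell cycle list 3 of 28 rose and none fell; Foxm1, a regulator of mitotic genes, rose by 1.86 ± 0.4 and the proliferation marker Mki67 by 1.35 ± 0.4. Of 15 tumour progression and dedifferentiation members 4 rose, 3 fell and 8 did not pass, with a median of -0.02 that became 2.03 scaled by the column total and 0.72 without mitochondrial genes. Cdh1, the adhesion protein of epithelia, rose by 1.66 ± 0.31, while Zeb1, its repressor, fell by 2.87 ± 0.41 and the filament gene Vim fell by 2.31 ± 0.34, falls that were not kept under both other scalings. Alveolar type 1 members went both ways, 3 rising and 4 falling of 12, and their median of -0.56 became 1.53 scaled by the column total and 0.2 without mitochondrial genes. Gprc5a and Aqp5 rose by 2.56 ± 0.39 and 2.25 ± 0.4, and Akap5 and Hopx were at -2.29 ± 0.36 and -1.93 ± 0.39, with Hopx at 0.16 scaled by the column total.

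Besides human EGFR, the genes that fell most in these tumours were Alb, which encodes albumin (-5.55 ± 0.75, log2, SE; 300.0 ± 347 with CMV-scrR, SD), Ddah1, which degrades an inhibitor of nitric oxide synthesis (-4.37 ± 0.57), and Erg, a transcription factor of endothelial cells (-4.24 ± 0.4). Nudt14 (-4.16 ± 0.56), the prostaglandin-degrading Hpgd (-4.06 ± 0.58), Rhox8 (-4.23 ± 0.68) and Serpina1b (-3.62 ± 0.68) fell too. With the mitochondrial share as a covariate Nudt14 was at 0.13. Hba-a2 fell by 5.86 ± 2.0, but is nearly identical to Hba-a1 and is uncertain. In the type I interferon list 10 of 21 fell, none rose and 11 did not pass, with a median of -1.22 that became 0.74 scaled by the column total and -0.51 without mitochondrial genes. Zbp1, a sensor of foreign nucleic acid, was at -2.32 ± 0.44 and Ifit3 at -1.89 ± 0.46 (0.2 scaled by the column total). For endothelium 4 of 13 fell, with Calcrl at -1.7 ± 0.39 (0.39 scaled by the column total), and the list median of -1.05 became 1.04 and -0.29 under those scalings. For macrophages 6 of 11 fell and 1 rose, with Adgre1 at -2.27 ± 0.54 (0.35 with the mitochondrial share as a covariate), and -1.07 became 1.02 and -0.31. Heat shock genes had 2 of 10 lower and a median of -0.69 that became 1.39 and 0.07, and oxidative phosphorylation genes 5 of 14 lower and -0.48 that became 1.61 and 0.28. The preset test called the interferon, endothelium, heat shock and oxidative phosphorylation lists, and all were lost with an estimated correlation (adjusted p = 0.979 for each).

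The difference between CMV-GE11-siRE and CMV-siRE tumours, whose circuits differ by the GE11 peptide, passed in 3 genes (n = 4 a group). The mitochondrial share differed too, at 20.6% and 60.1%, so the comparison does not isolate the peptide. Human EGFR fell as given above, Bglap3, of the osteocalcin family, rose by 3.12 ± 0.45 (log2, SE; adjusted p = 0.0451), and Gm20594, a predicted gene named after its value was seen, fell by 3.62 ± 0.54 (adjusted p = 0.0451). Of the lists, alveolar type 2 genes had a median of 1.03 with 9 of 16 higher and 1 lower adjusted over the list alone, and B and plasma cell genes a median of 2.11 over 11 members with none passing. Below 0 were heat shock (-0.77, 8 of 10 lower adjusted over the list alone; 0.84 and -0.18 under the total and the non-mitochondrial scaling), type I interferon (-0.78, 2 of 21; 0.78 and -0.24) and oxidative phosphorylation (-0.47, 0 of 14; 1.14 and 0.12). All 5 list calls were lost with an estimated correlation (adjusted p = 0.979 for each). At an unadjusted p under 0.05 there were 3677 genes. The count was 3176 without CMV-siRE replicate 1, 5 without CMV-GE11-siRE replicate 2, and 1 without CMV-siRE replicate 2, 3 or 4 or CMV-GE11-siRE replicate 1 or 3. It was 0 in a fit of only the 8 libraries and with the mitochondrial share as a covariate, 1 with a pseudocount of 0.1 and 11 with no filter on low values. Under the total and the non-mitochondrial scaling the median of all genes moved from 0.05 to 1.63 and 0.62 and the counts were 10826 (10788 higher, 38 lower) and 1912 (1852 higher, 60 lower).

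In the lungs, CMV-siRE changed 228 of 16165 genes against CMV-scrR, 78 rising and 150 falling (n = 4 a group). The genes that rose most included the serum amyloid genes Saa3 by 3.89 ± 0.35 (log2, SE; adjusted p = 0.000105) and Saa1, which shares reads with Saa2, by 4.3 ± 0.74, Serpina3k by 4.04 ± 0.83, Apoa1 by 3.31 ± 0.62 and Cxcl13, which attracts B cells, by 3.06 ± 0.38. Among those that fell most were Ido1, which degrades tryptophan, at -2.54 ± 0.5, the GTPase gene Igtp at -2.08 ± 0.29, Apol11b at -2.27 ± 0.26 and Zim1 at -3.04 ± 0.42; Gbp10 (-3.06 ± 0.47) belongs to a family of near-identical copies and is uncertain. In the type I interferon list 4 of 21 fell, among them Stat2 (-1.21 ± 0.21), Oasl2 (-1.28 ± 0.27) and Ifi44 (-1.43 ± 0.29). All 21 were lower adjusted over the list alone, with a median of -1.05 (adjusted p = 0.353 with an estimated correlation). CMV-scrR replicates 1 and 3 had interferon list means of 11.21 and 10.66 log2, against 9.76 and 9.9 in replicates 2 and 4, and without these 2 libraries the median was -0.42. Antigen presentation followed: the 3 of 20 that fell were Ciita (-1.37 ± 0.22), the peptide transporter Tap1 (-1.13 ± 0.2) and Nlrc5 (-1.15 ± 0.23), with 7 lower adjusted over the list alone (adjusted p = 0.745 with an estimated correlation).

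Erythroid genes fell in the same lungs. The haemoglobin gene Hbb-bt fell by 1.97 ± 0.17 (log2, SE; adjusted p = 9.47e-05), Alas2, which starts haem synthesis in red cells, by 1.98 ± 0.2, and Hba-a2, nearly identical to Hba-a1, by 1.84 ± 0.17. Of 12 members 5 fell and the median was -1.58 (adjusted p = 0.118 with an estimated correlation). The globin share of the column total was 0.37% ± 0.045 with CMV-scrR and 0.12% ± 0.031 with CMV-siRE (SD, n = 4). Macrophage genes rose, 4 of 14 with a median of 0.46, C1qb of the complement system by 0.92 ± 0.14 and Adgre1 by 0.94 ± 0.16 (adjusted p = 0.189 with an estimated correlation). Other lists called by the preset test were neutrophils, with a median of 0.66 and none of 12 passing (adjusted p = 0.745 with an estimated correlation), inflammatory cytokines, with 1 of 14 rising and a median of 0.39 (0.717), and cholesterol synthesis, with a median of 0.27 and 7 of 16 higher adjusted over the list alone (0.717). The medians were 0.3 for ciliated cells, 0.21 for alveolar type 2 cells, 0.12 for oxidative phosphorylation, -0.29 for heat shock and -0.13 for clock genes, and none of these calls held (adjusted p = 0.353 to 0.778). Of 10 glucocorticoid response genes 3 rose and 7 did not pass, with 2 lower adjusted over the list alone, a median of -0.06 and a mean of 0.23. Among them Lcn2, which binds bacterial siderophores, rose by 1.69 ± 0.36 and the metallothionein Mt2 by 1.68 ± 0.35. Timp1, an inhibitor of matrix proteases, rose by 1.43 ± 0.33. The clock repressor Nr1d1 fell by 0.99 ± 0.16, the MAPK inhibitor Spred2 by 0.6 ± 0.13 and the lipase Lipe by 0.83 ± 0.16. Scaled by the column total the split was 123 higher and 119 lower, and 126 and 114 without mitochondrial genes. Without CMV-scrR replicate 1 or 3 the count was 106 and 99, and without CMV-siRE replicates 1 to 4 in turn 131, 73, 113 and 104. It was 10 with the mitochondrial share as a covariate. That share was 1.74% to 1.98% with CMV-scrR and 2.23% to 2.51% with CMV-siRE, so the covariate can hardly be told apart from the circuit.

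With CMV-GE11-siRE against CMV-scrR in lung, limma called 0 genes, with 1277 at an unadjusted p under 0.05 (n = 4 a group). Interferon genes lay lower than the rest: 20 of 21 were lower adjusted over the list alone, the median was -1.12 (-0.52 without CMV-scrR replicates 1 and 3; adjusted p = 0.191 with an estimated correlation), and Oasl2 was at -1.22 ± 0.27 (log2, SE). Neutrophil genes had a median of -0.96 with Csf3r at -0.94 ± 0.33 (adjusted p = 0.547 with an estimated correlation), heat shock genes -0.33 with 3 of 10 lower adjusted over the list alone (adjusted p = 0.352 with an estimated correlation), and antigen presentation genes -0.27 with 8 of 20 (adjusted p = 0.415 with an estimated correlation). B and plasma cell genes had a median of 0.53, with Igkc at 0.91 ± 0.37 (adjusted p = 0.547 with an estimated correlation). The count was 29 without CMV-scrR replicate 2, 35 without CMV-scrR replicate 4 and 1 without CMV-GE11-siRE replicate 4.

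Between CMV-GE11-siRE and CMV-siRE lungs 10 genes changed, 7 rising and 3 falling (n = 4 a group). Red cell genes rose, Hbb-bt by 1.64 ± 0.17 (log2, SE; adjusted p = 0.00272), Alas2 by 1.63 ± 0.2, and the near-identical pair Hba-a2 and Hba-a1 by 1.46 ± 0.17 and 1.31 ± 0.16. Of 12 erythroid members 5 rose, with a median of 1.0 (adjusted p = 0.108 with an estimated correlation). Saa3 fell by 2.95 ± 0.35 and the protease inhibitor Serpina3n fell by 1.02 ± 0.16. Adjusted over the list alone, 12 of 12 neutrophil genes were lower (median -1.79; adjusted p = 0.252 with an estimated correlation) and 8 of 14 macrophage genes (median -0.51; adjusted p = 0.108 with an estimated correlation). Without CMV-GE11-siRE replicate 4 the count was 19.

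**Figure D2:**
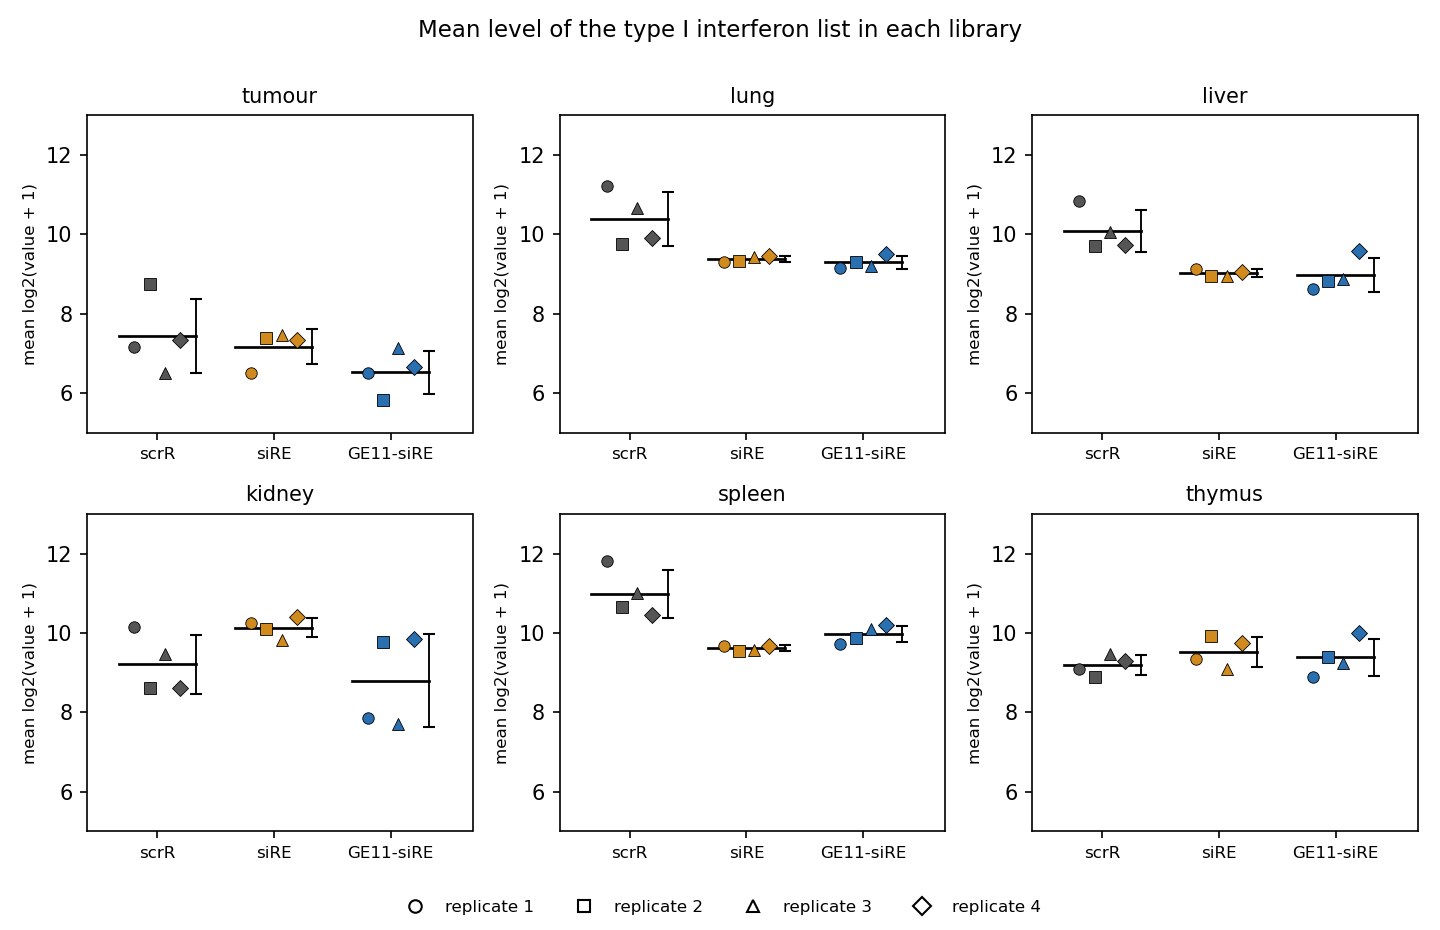
Mean log2(value + 1) of the 21 genes of the type I interferon list in each library of the 6 tissues, by circuit; lines are means of 4 libraries, bars are SD and symbols give the replicate number. In spleen all 8 libraries of both siRE circuits, at 9.55 to 10.2, lie below the 4 control libraries at 10.45 to 11.8.

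In liver, CMV-siRE changed 585 of 14484 genes against CMV-scrR, 299 rising and 286 falling (n = 4 a group). Saa3 rose by 6.53 ± 0.35 (log2, SE; adjusted p = 5.01e-07), from 211 ± 131 to 16700 ± 1610 (SD), with A2m, a protease inhibitor, up by 4.64 ± 0.83, the antibody gene Ighg2c up by 3.58 ± 0.44, and Saa2, which shares reads with Saa1 and is uncertain, up by 4.13 ± 0.66. Acute phase proteins followed: 5 of 16 rose and none fell, with a median of 0.43, including serum amyloid P (Apcs) by 1.27 ± 0.2 and Itih4 by 0.6 ± 0.11 (adjusted p = 0.506 with an estimated correlation). Of the glucocorticoid response list 4 of 10 rose, Lcn2 by 2.37 ± 0.48, the metallothionein Mt1 by 1.63 ± 0.32 and the kinase Sgk1 by 1.14 ± 0.22 (adjusted p = 0.309 with an estimated correlation). The calgranulin S100a9 rose by 1.43 ± 0.35, Timp1 by 2.63 ± 0.49, the VEGF receptor Kdr by 0.56 ± 0.13 and the lactate enzyme Ldha by 0.89 ± 0.13.

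Interferon genes fell in these livers, 12 of 21 with a median of -1.09 (-0.68 without CMV-scrR replicates 1 and 3) and all 21 adjusted over the list alone (adjusted p = 0.309 with an estimated correlation). The antiviral synthetases Oas3 and Oas2 were at -1.35 ± 0.22 and -1.25 ± 0.23 (log2, SE) and the interferon antagonist Usp18 at -1.13 ± 0.22. Fat burning genes fell too, 4 of 12 PPAR alpha targets with a median of -0.36: Acot1 (-1.68 ± 0.35), Angptl4, an inhibitor of lipoprotein lipase (-1.52 ± 0.23), Vnn1 (-1.13 ± 0.21) and Cpt1a, the entry step of fatty acids into mitochondria (-0.54 ± 0.11; adjusted p = 0.278 with an estimated correlation). The Kupffer cell gene Clec4f fell by 1.29 ± 0.28 and Hba-a2 by 1.67 ± 0.34, while the bile genes Abcb4 and Cyp27a1 fell by 0.46 ± 0.1 and 0.36 ± 0.08. Dusp8 (-3.08 ± 0.69), Gbp2b (-2.63 ± 0.45), Mup17 (-2.61 ± 0.51) and Mup15 (-2.52 ± 0.55) fell most, the last 3 being members of families with near-identical copies. Leaving out CMV-scrR replicate 1 or 3 gave 298 and 344 genes, and CMV-siRE replicate 2 or 3 179 and 204. With the mitochondrial share as a covariate the count was 193.

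CMV-GE11-siRE changed 612 liver genes against CMV-scrR, 317 rising and 295 falling (n = 4 a group). Saa3 rose by 5.78 ± 0.35 (log2, SE; adjusted p = 2.5e-06), Saa2 and Saa1 by 3.95 ± 0.66 and 3.12 ± 0.62, and 3 of 16 acute phase members passed with a median of 0.15 (adjusted p = 0.606 with an estimated correlation). Drug metabolism genes rose, 4 of 14 with none falling: Cyp1a1, a target of the aryl hydrocarbon receptor, by 3.37 ± 0.74, Cyp2b10 by 1.42 ± 0.3 and Cyp3a11 by 0.71 ± 0.18 (adjusted p = 0.398 with an estimated correlation). The interferon list had 13 of 21 lower and a median of -1.2 (-0.76 without CMV-scrR replicates 1 and 3), with Oasl2 at -1.51 ± 0.28 and the regulator Irf7 at -1.14 ± 0.19, and 19 lower adjusted over the list alone (adjusted p = 0.309 with an estimated correlation). Acod1, which makes itaconate in macrophages, fell by 2.97 ± 0.58, Selenbp2 fell by 2.86 ± 0.38, and Tgtp1 and Tgtp2, an interferon-inducible pair that shares reads, were at -2.77 ± 0.5 and -2.57 ± 0.38.

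In the same liver comparison 6 of 28 cell cycle genes fell, with a median of -0.93 and 18 lower adjusted over the list alone, among them the mitotic kinase Plk1 (-1.74 ± 0.28, log2, SE) and the cyclin Ccnb1 (-1.69 ± 0.34; adjusted p = 0.492 with an estimated correlation). Hspa1b, nearly identical to Hspa1a, fell by 2.23 ± 0.3, with 3 of 10 heat shock genes lower (adjusted p = 0.594 with an estimated correlation). The sterol hydroxylase Cyp8b1 fell by 1.92 ± 0.48 and Nr1d1 by 1.4 ± 0.34, while Elovl6, which lengthens fatty acids, rose by 1.1 ± 0.26, Pdk4 by 0.98 ± 0.24, and Dicer1, which processes small RNAs, by 0.46 ± 0.1. Macrophage genes Ctss and C1qa fell by 0.79 ± 0.14 and 0.59 ± 0.13. Leaving out CMV-scrR replicate 1 or 3 gave 303 and 341 genes, CMV-GE11-siRE replicate 1, 2 or 3 273, 310 and 406, and a fit of only the 8 libraries 258. With the mitochondrial share as a covariate the count was 234.

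CMV-GE11-siRE and CMV-siRE livers differed in 1 gene, Itgam, an integrin of myeloid cells, which fell by 1.27 ± 0.16 (log2, SE; adjusted p = 0.0275; n = 4 a group), and 1110 genes had an unadjusted p under 0.05. PPAR alpha targets lay higher, with a median of 0.49 and 8 of 12 higher adjusted over the list alone, a call that held with an estimated correlation (adjusted p = 0.0492). Cell cycle genes had a median of -0.73 with 4 of 28 lower adjusted over the list alone, neutrophil genes -1.01 with 3 of 9, and erythroid genes 0.56 with 4 of 9 higher (adjusted p = 0.309 for each with an estimated correlation). The Itgam call was lost when any of CMV-siRE replicates 1 to 4 or CMV-GE11-siRE replicates 1 to 3 was left out, and with the mitochondrial share as a covariate, with 0 genes each.

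In spleen, CMV-siRE changed 739 of 16015 genes against CMV-scrR, 277 rising and 462 falling (n = 4 a group). Marco, a scavenger receptor of marginal zone macrophages, rose by 2.39 ± 0.24 (log2, SE; adjusted p = 0.000147), and of 13 marginal zone and red pulp genes 7 rose and none fell, with a median of 0.73, including Cd5l by 1.27 ± 0.18, the iron exporter Slc40a1 by 0.93 ± 0.18 and Spic, which specifies red pulp macrophages, by 0.74 ± 0.13 (adjusted p = 0.0879 with an estimated correlation). Timd4, a receptor for dying cells, rose by 1.14 ± 0.18, Jchain of secreted antibodies by 1.24 ± 0.27 and Mzb1 by 0.77 ± 0.18. Mcf2 and Mybpc1 rose by 2.31 ± 0.32 and 2.25 ± 0.5. Interferon genes fell, 16 of 21 with a median of -1.19 (-0.7 without CMV-scrR replicates 1 and 3) and 20 adjusted over the list alone, with Rsad2, or viperin, at -2.82 ± 0.25, Isg15 at -2.47 ± 0.29 and Oasl2 at -2.17 ± 0.2 (adjusted p = 0.212 with an estimated correlation). Erythroid genes fell, 6 of 14 with a median of -1.16 and 13 adjusted over the list alone, with Alas2 at -2.33 ± 0.25 and Hbb-bs at -2.39 ± 0.27 (adjusted p = 0.295 with an estimated correlation). The globin share was 4.87% with CMV-scrR, 0.975% with CMV-siRE and 3.33% with CMV-GE11-siRE.

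Immediate early genes fell in these spleens, 7 of 15 with a median of -0.69 and 14 adjusted over the list alone, with Dusp1 at -0.89 ± 0.15, Junb at -0.83 ± 0.15 and Nr4a1 at -0.64 ± 0.11 (log2, SE; adjusted p = 0.171 with an estimated correlation). Heat shock genes fell, 5 of 10 with a median of -0.51, with Hspa1b, nearly identical to Hspa1a, at -2.02 ± 0.28 (adjusted p = 0.335 with an estimated correlation). The cyclin Ccnd1 (-0.67 ± 0.09), the MAPK phosphatase Dusp5 (-0.84 ± 0.13), the matrix gene Fn1 (-1.03 ± 0.15), the cytokine Tnf (-0.83 ± 0.16), granzyme Gzmb (-1.58 ± 0.26) and the neutrophil receptor Csf3r (-0.92 ± 0.18) fell. Of 20 antigen presentation genes 3 fell, with Nlrc5 and Tap1 at -0.81 ± 0.15 and -0.67 ± 0.14 (adjusted p = 0.335 with an estimated correlation). Apol10a (-3.28 ± 0.37), Apol11a (-3.26 ± 0.45), Apol11b (-3.18 ± 0.32) and Tmcc2 (-2.92 ± 0.33) fell most. Scaling without mitochondrial genes moved the median of all genes by 0.11, and the split became 699 higher and 347 lower, or 649 and 354 with the column total. Without CMV-siRE replicate 1, 2 or 3 the count was 442, 442 and 449, and with the mitochondrial share as a covariate it was 1. That share was 1.59% to 1.74% with CMV-scrR and 2.05% to 2.26% with CMV-siRE, so the covariate can hardly be told apart from the circuit.

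CMV-GE11-siRE changed 923 spleen genes against CMV-scrR, 367 rising and 556 falling (n = 4 a group). Of 16 T and NK cell genes 5 fell, none rose and 11 did not pass, with a median of -0.21 and 7 lower adjusted over the list alone, among them the cytotoxic genes Gzmb at -2.34 ± 0.26 (log2, SE; adjusted p = 0.00124), Gzma at -1.69 ± 0.32 and the pore protein Prf1 at -1.1 ± 0.17 (adjusted p = 0.335 with an estimated correlation). Of 12 neutrophil genes 4 fell, with Il1r2 at -1.74 ± 0.35 and Csf3r at -1.27 ± 0.18 (adjusted p = 0.459 with an estimated correlation). In the interferon list 13 of 21 fell with a median of -1.01 (-0.62 without CMV-scrR replicates 1 and 3) and 19 adjusted over the list alone, with Oasl2 at -1.62 ± 0.2 and the chemokine Cxcl10 at -1.44 ± 0.28 (adjusted p = 0.335 with an estimated correlation). Immediate early genes had 10 of 15 lower and a median of -0.7, with Junb at -0.97 ± 0.15, Atf3 at -1.34 ± 0.25 and Jun at -0.8 ± 0.15 (adjusted p = 0.171 with an estimated correlation). Heat shock genes had 6 of 10 lower, with Hspa1a, nearly identical to Hspa1b, at -2.32 ± 0.3 (adjusted p = 0.335 with an estimated correlation).

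The collagens Col1a1 and Col3a1 fell in these spleens (-0.84 ± 0.17 and -0.79 ± 0.15, log2, SE), with 6 of 15 matrix members lower. The class I antigen H2-K1 and Tap1 fell (-0.6 ± 0.13 and -0.72 ± 0.14), with 7 of 20 antigen presentation members lower (adjusted p = 0.335 for each list with an estimated correlation). Dusp5 and Ccnd1 were at -1.1 ± 0.13 and -0.59 ± 0.09. Marco rose by 1.45 ± 0.24, the haemoglobin scavenger receptor Cd163 by 1.26 ± 0.31, Slc40a1 by 0.78 ± 0.18, Cd5l by 0.68 ± 0.18 and Spic by 0.5 ± 0.13, with 5 of 13 marginal zone and red pulp genes higher (adjusted p = 0.212 with an estimated correlation). Zbed6, which lies in an intron of another gene and is uncertain, rose by 6.19 ± 1.16, Mybpc1 by 2.02 ± 0.5 and the eosinophil peroxidase Epx by 1.81 ± 0.39. Prr18 (-2.95 ± 0.67), Acod1 (-2.61 ± 0.57), Ly6i (-2.4 ± 0.36) and Apol11a (-2.35 ± 0.45) fell most. The split was 529 higher and 398 lower scaled by the column total and 559 and 385 without mitochondrial genes. Counts were 249 and 520 without CMV-scrR replicate 1 or 3, 241, 182 and 448 without CMV-GE11-siRE replicate 1, 3 or 4, 554 with no filter on low values, 340 in a fit of only the 8 libraries, and 0 with the mitochondrial share as a covariate. That share was 1.59% to 1.74% with CMV-scrR and 1.9% to 2.18% with CMV-GE11-siRE, so here too the covariate can hardly be told apart from the circuit.

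Between CMV-GE11-siRE and CMV-siRE spleens 18 genes changed, 15 rising and 3 falling (n = 4 a group). Red cell genes rose, 5 of 14 erythroid members with a median of 1.31 and 11 adjusted over the list alone, Hbb-bs by 1.93 ± 0.27 (log2, SE; adjusted p = 0.01) and Alas2 by 1.92 ± 0.25 (adjusted p = 0.212 with an estimated correlation). Bpgm, which makes the regulator of oxygen release in red cells, rose by 1.94 ± 0.24, Tmcc2 by 2.06 ± 0.33, the interleukin subunit Il12b by 2.06 ± 0.3, Apol7c by 2.11 ± 0.24 and the interferon gene Rsad2 by 1.81 ± 0.25. Cd7, of T and NK cells, fell by 0.83 ± 0.11. Cell cycle genes had a median of 0.43 with 13 of 28 higher adjusted over the list alone (adjusted p = 0.335 with an estimated correlation). The count was 38 without CMV-siRE replicate 1, 10 without CMV-siRE replicate 2 or 4, 2 without CMV-GE11-siRE replicate 3, and 10 with the mitochondrial share as a covariate.

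In kidney, limma called 0 of 15105 genes in each comparison, with 1486, 1218 and 599 genes at an unadjusted p under 0.05 for CMV-siRE against CMV-scrR, CMV-GE11-siRE against CMV-scrR and CMV-GE11-siRE against CMV-siRE (n = 4 a group). The circadian clock list stood out for CMV-siRE: 9 of 15 members were higher and 2 lower adjusted over the list alone, with a median of 0.9 (adjusted p = 0.422 with an estimated correlation). Its abundant kidney members Tef and Hlf were at 1.04 ± 0.27 and 0.73 ± 0.21 (log2, SE). With Dbp as a covariate Tef was at -0.1. Since Dbp is itself a clock gene, that covariate takes out clock differences and cannot test them. Fitted on only the 8 libraries of these groups, 1093 genes passed, and 8 of the clock genes rose and 3 fell. Dbp, an output gene of the clock chosen after its values were seen, rose by 4.09 ± 0.29 from 74.7 to 1310 (adjusted p = 0.000427), and the core activators Npas2 and Arntl were at -4.64 ± 0.33 and -3.25 ± 0.31. In all 12 libraries Dbp was 55.8 to 109 with CMV-scrR, 871 to 2108 with CMV-siRE, and with CMV-GE11-siRE 78.8, 1321, 52.9 and 790 in replicates 1 to 4. The count was 1 without CMV-siRE replicate 1, 37 without CMV-GE11-siRE replicate 4 and 4 with the mitochondrial share as a covariate.

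Other kidney lists called by the preset test for CMV-siRE against CMV-scrR were tubular injury, with a median of 1.01 and its abundant members Spp1 and C3 at 0.77 ± 0.37 and 2.19 ± 0.99 (log2, SE), type I interferon (0.99), neutrophils (1.12), proximal tubule (-0.44, the transporter Slc34a1 at -0.67 ± 0.3) and distal nephron (-0.35, the salt transporter Slc12a3 at -0.73 ± 0.22); none held (adjusted p = 0.64 for each with an estimated correlation). The kidney group given CMV-GE11-siRE was uneven: replicate 4 had r = 0.8921 to 0.938 with the other 3 across genes, which are not independent replicates, and Dbp split the group as given above. For CMV-GE11-siRE against CMV-scrR, T and NK cell genes had a median of 0.98, matrix genes 0.7 and interferon genes -0.37 (adjusted p = 0.64, 0.64 and 0.708 with an estimated correlation). Between CMV-GE11-siRE and CMV-siRE, interferon genes had a median of -1.35 with 6 of 21 lower adjusted over the list alone, and clock genes -0.58 with 2 of 15 higher and 5 lower (adjusted p = 0.577 and 0.422 with an estimated correlation). The interferon list means were 7.85, 9.78, 7.71 and 9.85 log2 in CMV-GE11-siRE replicates 1 to 4, against 9.81 to 10.4 with CMV-siRE. They split the group along the same replicates as Dbp.

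**Figure D3:**
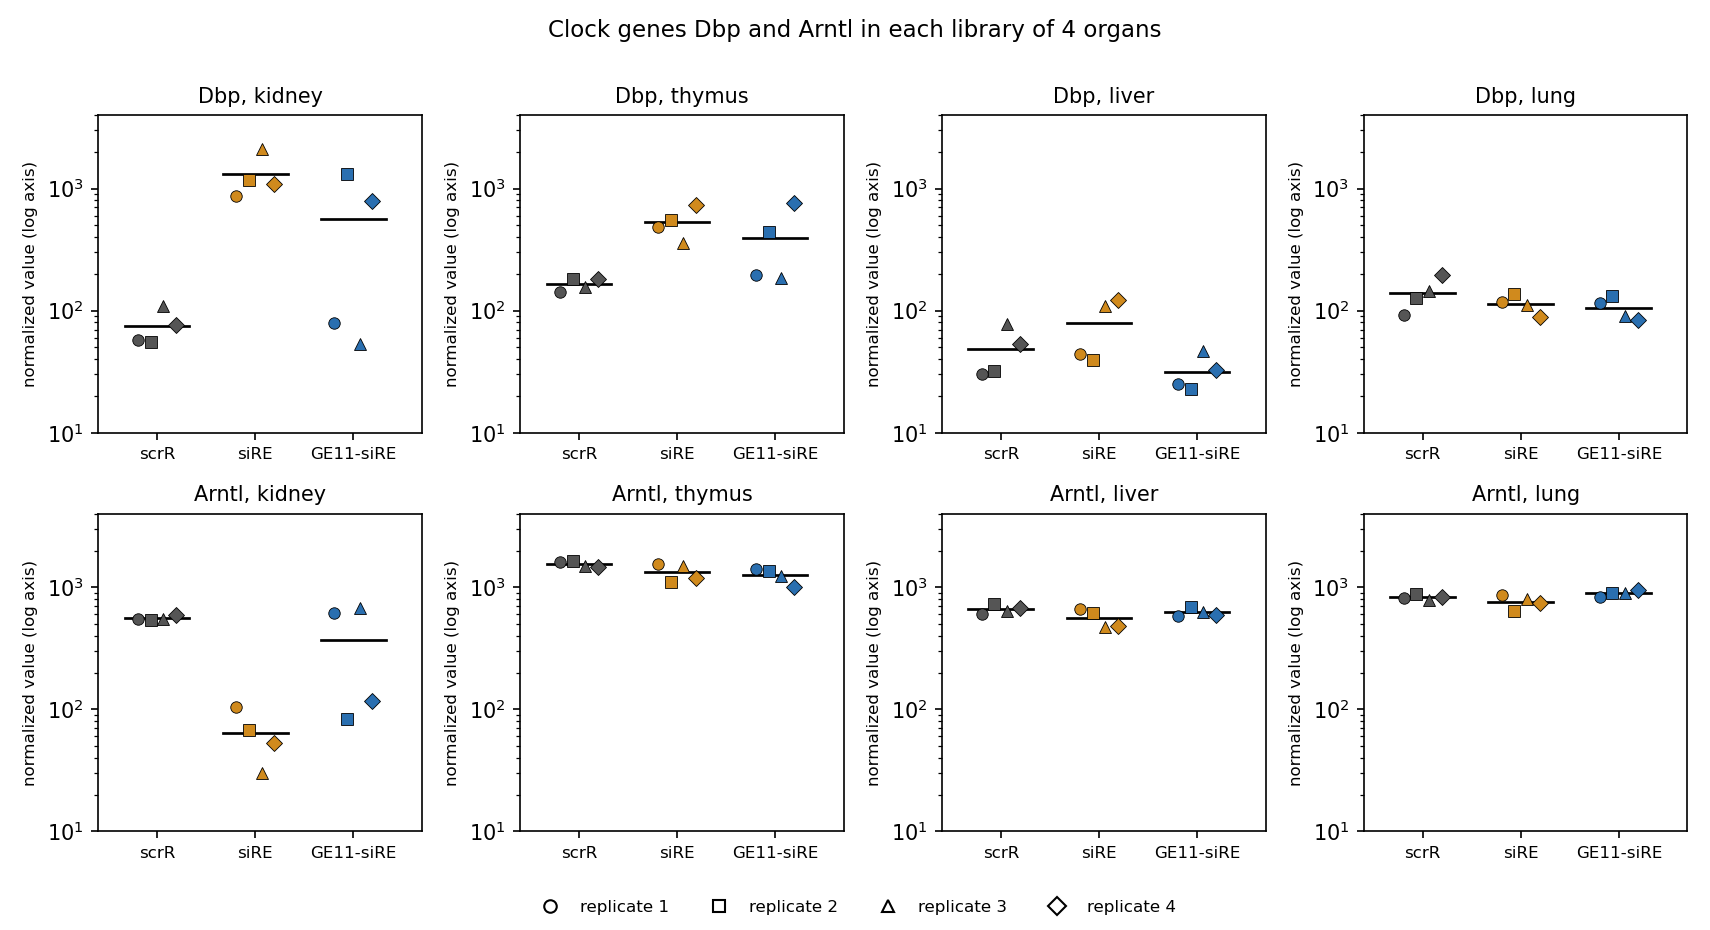
Normalized values (log axes) of Dbp and Arntl in each library of kidney, thymus, liver and lung, by circuit; lines are means of 4 libraries and symbols give the replicate number. In kidney, CMV-GE11-siRE replicates 2 and 4 have Dbp at 1321 and 790, and replicates 1 and 3 at 78.8 and 52.9.

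In thymus, 1 of 16421 genes changed with CMV-siRE against CMV-scrR, the predicted gene Gm6649, named after its value was seen, which fell by 5.1 ± 0.57 (log2, SE; adjusted p = 0.0144; n = 4 a group). At an unadjusted p under 0.05 there were 927 genes. The other comparisons had 0 genes in limma, with 1550 for CMV-GE11-siRE against CMV-scrR and 461 for CMV-GE11-siRE against CMV-siRE. For CMV-siRE against CMV-scrR 6 of 15 clock genes were higher and 1 lower adjusted over the list alone, with a median of 0.24 (adjusted p = 0.332 with an estimated correlation). Cell cycle genes lay lower, with a median of -0.4 and Top2a at -0.58 ± 0.44, or 1.0 with Dbp as a covariate (adjusted p = 0.749 with an estimated correlation). In a fit of only the 8 libraries 1673 genes passed. Of the clock genes 6 rose and 2 fell, Dbp by 1.63 ± 0.2, Per3 by 1.18 ± 0.15 and Nr1d1 by 1.39 ± 0.18, and of 28 cell cycle genes 8 fell. B and plasma cell genes had a median of 0.56 in both comparisons with CMV-scrR, with Igkc at 1.22 ± 0.55 and 0.79 ± 0.55 (-0.58 and -0.32 with Dbp as a covariate), and oxidative phosphorylation genes 0.27 and 0.2 with CMV-GE11-siRE against CMV-scrR and against CMV-siRE (adjusted p = 0.749 for each with an estimated correlation). The Gm6649 call was lost, with 0 genes, when any of CMV-scrR replicates 1 to 4 or CMV-siRE replicates 1 to 4 was left out, with a pseudocount of 0.1, and with Dbp as a covariate. In that comparison 1773 genes passed without CMV-GE11-siRE replicate 4 and 2817 with the mitochondrial share as a covariate. For CMV-GE11-siRE against CMV-scrR 1 gene passed without CMV-GE11-siRE replicate 2, 2 with no filter on low values and 739 with the mitochondrial share as a covariate, and without replicate 4 1 passed for CMV-GE11-siRE against CMV-siRE.

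The comparisons of both siRE circuits with CMV-scrR share their control libraries, which alone makes their fold changes alike. In liver 170 genes rose and 139 fell in both, in spleen 137 and 230, and in tumour 30 and 4. Lists of the same sizes drawn independently, a value that leaves out the shared controls, would share 6.54 and 5.83 in liver, 6.35 and 16 in spleen and 6.86 and 0.991 in tumour. In 20 simulations of unchanged groups against shared controls, a value that leaves out real effects and noise shared between genes, the mean was 0 in these 3 tissues. With different controls for each comparison, 2 and 2 in 6 splits, 19 to 34 rose and 8 to 16 fell in both in liver, 3 to 30 and 14 to 59 in spleen and 0 to 240 and 0 to 176 in tumour. Lung, kidney and thymus had 0 in both, since no gene was called for CMV-GE11-siRE against CMV-scrR. Across genes, which are not independent replicates, the correlation of the fold changes was 0.809 in tumour, 0.619 in lung, 0.712 in liver, 0.676 in kidney, 0.69 in spleen and 0.76 in thymus, where simulated unchanged groups gave 0.498 to 0.504. The simulated noise was independent between genes. That narrow range therefore follows from the shared controls alone and cannot show whether the observed values exceed noise shared by many genes. With different controls for each comparison it averaged 0.557, 0.258, 0.375, 0.414, 0.366 and 0.494 in the same order. The covariance was 0.783, 0.0853, 0.136, 0.147, 0.144 and 0.158, and the simulated covariance 0.118, 0.0364, 0.0393, 0.0639, 0.0394 and 0.0596.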

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

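The test of composition that goes with the mitochondrial share was written before its result was seen; the other tests in this part were chosen after the result was seen. Of 75 groups of 4 libraries tested for a library far from the others, 7 were marked, where 3.75 would be expected, since chance flags about 1 in 20 groups. Differences between tissues below were not tested. They were marked because every library of the circuit lay above the mean of the controls in 1 tissue and below it in another. Single control libraries could still overlap with them.

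Human EGFR was lower in tumours given CMV-GE11-siRE, and 5890 genes changed in that comparison. Column scaling as the cause is argued against for human EGFR, whose difference closest to 0 over the other scalings was -3.11 in limma (-3.0 as a difference of means in log2(CPM + 1)), but stays open for the broad changes: both other scalings move all genes up, so the 100% of higher and 2% of lower calls that stayed decide nothing. The alveolar type 2 score minus the endothelium score was higher by 2.99 log2 (exact permutation p = 0.0286). It speaks against more normal lung only if normal lung raises both kinds of marker alike. That need not hold where tumours have endothelium of their own, so more normal lung stays open. Composition that goes with the mitochondrial share stays open for the broad changes: across called genes the within-group slope and the fold change had r = -0.7 (-0.52 over all genes), though the slope predicted 0.06 for human EGFR. With that share as a covariate human EGFR went from -5.19 ± 0.38 to -5.25 ± 0.95 and lost the call (limma adjusted p = 0.99). The difference hardly changed, while the median standard error of all genes rose from 0.34 to 0.81 and 0 genes passed.

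Type I interferon list medians lay below 0 in lung, liver and spleen with both siRE circuits, though none of 21 members passed in lung with CMV-GE11-siRE and no list call held with an estimated correlation (adjusted p = 0.191 to 0.353). By column total the list median closest to 0 over the 6 comparisons was -0.95. The median of all genes was then only -0.02 to 0.1, so this scaling could hardly move the list and does not test scaling as a cause. In each comparison an immune cell list lay at least 1.05 above the interferon list. It was picked as the largest gap among lists at the smallest exact permutation p, 0.0286, so that p is no test of it. The gaps argue only against an equal fall of every immune cell list. Fewer cells of 1 kind stay open: in lung with CMV-GE11-siRE the neutrophil list lay 0.16 above the interferon list, while in the other 5 comparisons the smallest gap of any immune list was 0.57 to 1.09 and neutrophil medians were 0.66 in lung and 0.9 in liver with CMV-siRE. A high level in CMV-scrR replicates 1 and 3 alone is argued against as the whole cause by the median closest to 0 without them, -0.42, against -1.01 to -1.2 with them. Whether the control circuit raised these genes or the siRE circuits lowered them stays open, since no group without a circuit was compared, and a batch that goes with the circuits was not tested.

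Clock genes differed between kidney libraries and between thymus libraries. Among the CMV-GE11-siRE libraries the larger spread in Dbp of liver and lung was 1.01 log2. Within that group this argues against all organs of a mouse taken at another time of day. It does so only if its organ libraries come from the same mice, which was not established. It cannot see a time of day that differed between circuits. In lung Nr1d1 was 1510 to 2111 with CMV-scrR and 869 to 1059 with CMV-siRE. The circuit as the whole cause is argued against by a spread in Dbp of 4.62 log2 among the 4 CMV-GE11-siRE kidneys. A time of removal that differed for kidney and thymus alone stays open and was not tested. In kidney 1093 genes were called for CMV-siRE against CMV-scrR in the 8 libraries, against at most 2 in the other splits.

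Of libraries far from their group, tumour CMV-siRE replicate 4 had 1.25% globin (others 0.00283% to 0.15%), and kidney CMV-siRE replicate 1 had 0.0772% (others 0.026% to 0.0296%). Tumour CMV-siRE replicate 1 had an interferon list mean of 6.5 log2 (others 7.34 to 7.45). Egfr was 4113.0 in liver CMV-GE11-siRE replicate 4 (others 3760.0 to 3820.0) and 199.0 in thymus CMV-siRE replicate 3 (others 517.0 to 562.0). The mitochondrial share was 1.64% in thymus CMV-siRE replicate 1 (others 1.84% to 1.88%) and 0.558% in thymus CMV-GE11-siRE replicate 4 (others 1.9% to 1.92%).

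Between tissues, the interferon list mean with CMV-siRE against CMV-scrR differed by -1.01 in lung, -1.06 in liver and -1.36 in spleen, and by 0.919 in kidney. In kidney the groups overlapped: CMV-scrR replicate 1, at 10.15 log2, lay above CMV-siRE replicates 2 and 3, at 10.09 and 9.81. Among CMV-GE11-siRE kidneys the list mean was 7.85 and 7.71 in replicates 1 and 3, where Dbp was low. It was 9.78 and 9.85 in replicates 2 and 4, where Dbp was high. Kidney Dbp was 55.8 to 109 with CMV-scrR and 871 to 2108 with CMV-siRE. The kidney difference of CMV-siRE from CMV-scrR therefore cannot be told apart from that in Dbp. The mitochondrial share in the same comparison differed by 0.508 points in lung and 0.47 in spleen, and by -0.57 in liver and -1.87 in kidney. With CMV-GE11-siRE against CMV-scrR it differed by -48.0 points in tumour, 0.567 in lung and 0.331 in spleen.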

How the results depend on the processing

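Scalings by total, the covariates and the fits of kidney and thymus without CMV-GE11-siRE replicate 4 were chosen after the result was seen; the other settings were planned. DESeq2 size factors and relative log expression on counts were not run, because the files hold normalized values. Of 281 comparison counts 179 kept within 1.5 times and 102 moved; of 371 values of human EGFR and Egfr 324 stayed the same. Of 1443 list results 1162 stayed the same, 279 lost the call and 2 reversed, and of 4045 results for named genes 3366 stayed the same, 657 lost the call, 12 gained it and 10 reversed. A list counted as reversed when the direction of its test changed, not when its median changed sign. Unless a reason is given, the cause was not tested.

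Comparisons below are CMV-siRE against CMV-scrR (E), CMV-GE11-siRE against CMV-scrR (G) and CMV-GE11-siRE against CMV-siRE (D). With a pseudocount of 0.1 the count became 0 in thymus E and 1 in tumour D. With no filter it became 554 in spleen G, 2 in thymus G, 11 in tumour D and 16 in tumour E. With only the 8 libraries it became 1093 in kidney E, 258 in liver G, 340 in spleen G, 1673 in thymus E, and 0 in tumour D and in tumour E. Human EGFR in D (-3.31) and Egfr in liver G (-0.37) then lost the call.

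With the replicate number as a block the count became 2 in liver D, 258 in spleen G, 0 in thymus E, 7 in tumour D and 190 in tumour E, where human EGFR, at -1.88, passed. The correlation between libraries of the same number, paired across groups, was -0.144 to 0.215 in tumour, and over 0.1 in 2 of 12 pairs there, so the numbers gave little sign of a pairing.

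Divided by the column total the count became 11435 in tumour G, 10826 in tumour D and 11 in tumour E, and by the total without mitochondrial genes 1912 in D and 14 in E. Egfr by column total was 0.05 in spleen G and 0.41 in tumour E, both reversed, and passed in tumour G (2.49) and D (2.08). Without mitochondrial genes it reversed in spleen G (0.06) and tumour E (0.09). By column total the direction of the list test reversed for oxidative phosphorylation in tumour G (median 1.61) and D (1.14). List medians also changed sign without counting as reversed, among them type I interferon (0.74), heat shock (1.39) and endothelium (1.04) in tumour G. In tumour D they included type I interferon (0.78) and heat shock (0.84). Calcrl (0.39), Hopx (0.16), Ifit3 (0.2) and Zeb2 (0.03) reversed by column total in tumour G. As differences of group means, human EGFR was -3.0 in G and -1.63 in D in log2(CPM + 1), -3.11 and -1.71 in log2(CPM + 0.1), and Egfr in tumour G 1.78 and 2.43. The larger shift of all genes by column total follows from the mitochondrial share.

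With the mitochondrial share as a covariate the count became 4 in kidney E, 234 in liver G, 0 in liver D, 193 in liver E, 10 in lung E, 0 in spleen G, 10 in spleen D, 1 in spleen E, 739 in thymus G, 2817 in thymus E, 0 in tumour G, 0 in tumour D and 7 in tumour E. In lung and spleen every library of both siRE circuits had a higher share than all controls. In E and G of these organs the covariate can hardly be told apart from the circuit. Human EGFR lost the call in G, from -5.19 ± 0.38 to -5.25 ± 0.95, and in D, from -3.31 ± 0.38 to -3.36 ± 0.81 (adjusted p = 1). Its differences hardly changed, while the median standard error of all genes rose from 0.34 to 0.81 and 0.69. In E human EGFR was at -1.9 ± 0.42 (adjusted p = 0.14). Egfr lost the call in liver G (-0.38) and reversed in tumour G (-1.73) and D (-1.24), and Adgre1 (0.35) and Nudt14 (0.13) reversed in tumour G. With Ddx3y as a covariate tumour E had 1100 genes and human EGFR, at -1.85, passed. With Dbp as a covariate thymus E had 0 genes, and Egfr reversed in kidney G (0.06), kidney E (0.32) and thymus E (-0.3), as did Tef in kidney E (-0.1), Top2a in thymus E (1.0) and Igkc in thymus E (-0.58) and G (-0.32).

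The correlation of both siRE effects, with the controls split 2 and 2, was 0.414 in kidney, 0.375 in liver, 0.258 in lung, 0.366 in spleen, 0.494 in thymus and 0.557 in tumour, since the comparisons then share no control. An estimated correlation ended 110 of 111 list calls, and fry in place of camera 82 of 111.

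Leaving out 1 library, in the order E, G, D, gave counts of 1 to 798, 4384 to 5376 and 1 to 3176 in tumour, 73 to 189, 0 to 35 and 8 to 19 in lung, and 179 to 533, 273 to 674 and 0 to 1 in liver. They were 0 to 37, 0 to 0 and 0 to 0 in kidney, 442 to 642, 182 to 1233 and 2 to 38 in spleen, and 0 to 1773, 0 to 1 and 0 to 1 in thymus. Human EGFR ranged from -2.14 to -1.62, -5.44 to -4.86 and -3.57 to -2.98. Egfr ranged in tumour from -0.77 to 0.69, 0.29 to 0.74 and -0.24 to 1.22, in lung from -0.46 to -0.25, -0.24 to -0.08 and 0.09 to 0.29, and in liver from -0.19 to -0.07, -0.44 to -0.31 and -0.28 to -0.22. In kidney it ranged from -0.13 to 0.04, -0.2 to 0.06 and -0.17 to 0.09, in spleen from -0.63 to -0.02, -0.26 to 0.35 and 0.2 to 0.47, and in thymus from -0.02 to 0.47, -0.2 to 0.05 and -0.57 to -0.07.

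At an approximate depth of 12.2 M to 20.9 M a library, genes of low abundance are below the filter, and their changes cannot be read from these values.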

Other observations

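The test of GC content was written before its result was seen; the other test, the splits and the genes in this part were chosen after the result was seen.

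Igtp, Irgm2 and Iigp1 are interferon-inducible GTPases, which act on vacuoles that hold pathogens; they were picked after their values were seen and not tested as a group. In liver Igtp fell, at -1.79 ± 0.38 with CMV-siRE against CMV-scrR (log2, SE; adjusted p = 0.02) and at -2.05 ± 0.38 with CMV-GE11-siRE (adjusted p = 0.0107), and in spleen was at -1.45 ± 0.23 and -1.32 ± 0.23 (adjusted p = 0.00377 and 0.0115; n = 4 a group). Irgm2 was at -1.2 ± 0.23 and -1.32 ± 0.23 in liver, and at -1.28 ± 0.21 and -1.11 ± 0.21 in spleen, all of which passed. Iigp1 was at -1.42 ± 0.33 and -1.61 ± 0.33 in liver and at -1.53 ± 0.35 and -1.4 ± 0.35 in spleen, which passed too. In lung with CMV-siRE, Irgm2 fell by 1.65 ± 0.22 and Iigp1 fell by 1.84 ± 0.27 (adjusted p = 0.00276 and 0.00545), while with CMV-GE11-siRE Igtp, Irgm2 and Iigp1 were at -1.7 ± 0.29, -1.27 ± 0.22 and -1.38 ± 0.27 and did not pass (adjusted p = 0.101, 0.101 and 0.116). Cxcl9, a T cell chemokine also induced by interferon, went the other way in liver, where it rose by 2.84 ± 0.34 with CMV-siRE and by 2.0 ± 0.34 with CMV-GE11-siRE (adjusted p = 0.00104 and 0.00778).

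Ddx3y, a gene of the Y chromosome, was high in 4 of 12 tumour libraries and far lower in the organ libraries of the same number. It was 418 in CMV-scrR replicate 2, 400 and 330 in CMV-siRE replicates 2 and 4, and 422 in CMV-GE11-siRE replicate 2, where the highest organ values were 18.4, 11, 12.9 and 12.3. This argues against tumour and organ libraries of the same number coming from the same mouse.

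Kidney and thymus libraries of CMV-GE11-siRE replicate 4 stood apart from the other libraries of their group. Across genes, which are not independent replicates, their difference from the others of their group had a Spearman rho of at least 0.61 with GC content, so a GC bias of these libraries may explain it. Their mitochondrial share was low as well, at 3.69% in kidney and 0.56% in thymus (others of the group 10.73% to 12.66% and 1.9% to 1.92%). Fold changes of comparisons had rho from -0.43 in spleen to 0.5 in thymus, both for CMV-GE11-siRE against CMV-scrR. For CMV-siRE against CMV-scrR, whose groups do not hold these libraries, rho was 0.32 in kidney and 0.47 in thymus. A trend with GC content was thus not particular to them.

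All 35 splits of the 8 libraries of a comparison into 4 and 4 were fitted, to ask only whether a grouping by chance can be excluded. The real grouping, then the highest of the others, gave for CMV-siRE against CMV-scrR 0 and 1 genes in tumour, 303 and 1 in lung, 492 and 1 in liver, 1093 and 2 in kidney, 656 and 1 in spleen and 1673 and 24 in thymus. For CMV-GE11-siRE against CMV-scrR they were 6709 and 0 in tumour, 0 and 2 in lung, 258 and 1 in liver, 0 and 1 in kidney, 340 and 0 in spleen and 0 and 1 in thymus. For CMV-GE11-siRE against CMV-siRE they were 0 and 1 in tumour, 9 and 1 in lung, 1 and 10 in liver, 0 and 0 in kidney, 18 and 10 in spleen and 0 and 1 in thymus. Where no gene was called all 35 splits reached the real count, and chance was not excluded. Nor was it for CMV-GE11-siRE against CMV-siRE in liver, where 4 splits reached the real count of 1 and the highest of the others called 10 genes. Elsewhere 1 split, the real one, reached its count.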
